A study of Homo sapiens with 8 samples.

How the data were processed

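Gene expression was measured by RNA sequencing in 8 libraries of MCF7 cells, 4 labelled refed and 4 labelled starved. Per the labels' protocols, cells grown with 10% serum were seeded 2 days before the experiment, RNA was extracted with TRIzol, and 1.0 µg of total RNA went into each library made with an NEBNext Ultra kit. Per the submitters' processing notes, HISAT2, featureCounts and the human build hg38 were used; their versions, the gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The authors deposited raw read counts per gene symbol, 1 column per library, and no row was 0 in every library. Column names matched the description labels of the samples. The counts were whole numbers that summed to between 14702280 and 19654725 per library. At these totals, the self-test below gives the precision.

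Symbols were matched to GENCODE release 29 (GRCh38): 33166 of 35978 matched by symbol and 851 through a current symbol and its gene ID, 43 named several genes and 1918 had no match. GC content and length were taken from the longest transcript of each gene, and the share of exon length overlapping other genes from the same annotation. Of the tested genes, 98.2% had a transcript value.

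Counts were analysed with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 in R 4.3.3; figures were drawn in Python 3.11.15 with matplotlib 3.10.9. Genes were kept by filterByExpr with its minimum count of 10, which left 16303, and libraries were scaled by TMM. The main test was the two-sided quasi-likelihood test (glmQLFit, robust, glmQLFTest) of group alone, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Changes beyond 1.5-fold were tested with glmTreat. Log2 fold changes are labelled refed minus labelled starved, and their SE is the log2 fold change over the root of the F statistic. CPM values are TMM-scaled; log2 CPM values had a prior count of 2. Gene lists with at least 5 tested members were tested with camera (preset correlation 0.01, and an estimated one) and fry on voom values, with adjustment over the lists. Single library measures were compared by exact permutation of the 8 libraries.

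The comparison, tests, gene lists and named genes were fixed before the data were examined. Named genes were the 12 largest increases and 12 largest decreases among genes called at 0.05 with a mean CPM of at least 5 and no overlap between the groups; up to 4 members with the smallest p of each list described, with a mean CPM of at least 1; and always TXNIP, ARRDC4, SLC2A1, HK2, DDIT4, ASNS, HSPA5 and MYC, the first pair as a check of the glucose labels. The alternatives fixed at the same time were the replicate number as a block, DESeq2, limma-voom, other scalings, other filters on low counts, the removal of mitochondrial and the 20 most abundant genes, thinning to the smallest library, each library left out, a threshold of 0.01, and other list tests. After the GC trend was seen, fits were added in which a loess trend (span 0.3) on transcript GC, or on GC and then log2 length, was removed from each library as an offset.

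No pair of libraries of a group agreed within sampling noise: over genes with at least 50 counts the chi-square statistic divided by its degrees of freedom ranged from 2.60 to 8.60. The labels call the samples biological replicates but do not say how the cultures were separated.

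The scripts were tested on simulated data, and the part with a GC trend was added after that trend was seen. Counts were drawn for the real genes with the real library sizes and dispersions, with 50 genes changed at each of 4 fold sizes between the simulated refed and starved libraries. Over 16059 genes, 40% of changes of 1.25-fold, 82% of 1.5-fold, 86% of 2-fold and 100% of 4-fold were recovered, and 13 of 15859 unchanged genes were called. With a GC trend of the size seen here added, 5749 of 15809 otherwise unchanged genes were called over 16009 genes; with GC and length offsets 9 of 15540 were, and recovery over 15740 genes was 50%, 78%, 88% and 100% in the same order of folds. A list raised by 0.3 on the log2 scale was the only one called, and the GC trend alone shifted 3 lists without and 0 with the offsets. Genes were drawn independently of one another, so these runs could not show false list calls from correlated members. The simulated trend was linear in the GC values that the offsets use and equal in all simulated refed libraries. Its removal was therefore easier than that of the real trend, whose slope varied between libraries.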

Results

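Messenger RNA was measured by RNA sequencing in MCF7 cells, an estrogen receptor positive epithelial line derived from a breast cancer. The series asked how glucose refeeding after a short glucose withdrawal changes gene expression. Per the labels, both groups were given fresh medium for 4 h and then glucose-free medium for 4 h. The refed group was then returned to complete medium before collection. The length of that last step is not given in the sources used here. There were 4 libraries labelled refed and 4 labelled starved, described as biological replicates. Total counts ranged from 14702280 to 19654725 per library, with no detected difference between the groups (exact two-sided permutation test, p = 0.914, n = 4 per group). Of 35978 gene symbols, 16303 had enough counts to be tested. There was no group of cells kept in glucose throughout, so each comparison is between refed and starved cells alone. Refeeding also renewed the whole medium.

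The 2 genes fixed in advance as a check of the glucose labels went against them. TXNIP, an arrestin-like inhibitor of glucose uptake whose transcription is induced by glucose through the factor MondoA, stood at 13.9 ± 0.670 CPM (SD, n = 4) in the libraries labelled refed and at 199 ± 3.77 CPM in those labelled starved, a 14.3-fold lower level in labelled refed (log2 fold change -3.84, SE 0.06, edgeR quasi-likelihood adjusted p = 1.444e-30). ARRDC4, its close relative and a further MondoA target, stood at 15.0 ± 0.865 CPM in labelled refed and 78.6 ± 3.59 CPM in labelled starved (log2 fold change -2.39, SE 0.07). TXNIP lies on chromosome 1 at 145992435 to 145996600 and ARRDC4 on chromosome 15 at 97960698 to 97973838 (GRCh38, GENCODE release 29), and the exons of neither overlap another gene. In every library labelled refed both genes were below every library labelled starved. Directions are therefore given for the libraries as labelled. Each of them would turn round if the labels were exchanged. Among 10 tested members of the MondoA and ChREBP glucose-response list, 3 were higher and 3 lower in labelled refed, and 4 did not pass the test. KLF10, a transcriptional repressor, was lower (log2 fold change -0.37, SE 0.06) and TKFC, a fructose-handling kinase, was higher (0.33, SE 0.06). The list as a whole did not shift (camera adjusted p = 0.408), and its median log2 fold change of 0.09 and mean of -0.51 differ in sign. With the trends of GC content and transcript length described below removed, 1 member was higher and 3 lower, and the list passed as lower (adjusted p = 0.024, and 0.195 with an estimated correlation). TKFC then stood at 0.14, and with GC alone removed at 0.11 without passing (edgeR adjusted p = 0.0714).

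**Figure D1:**
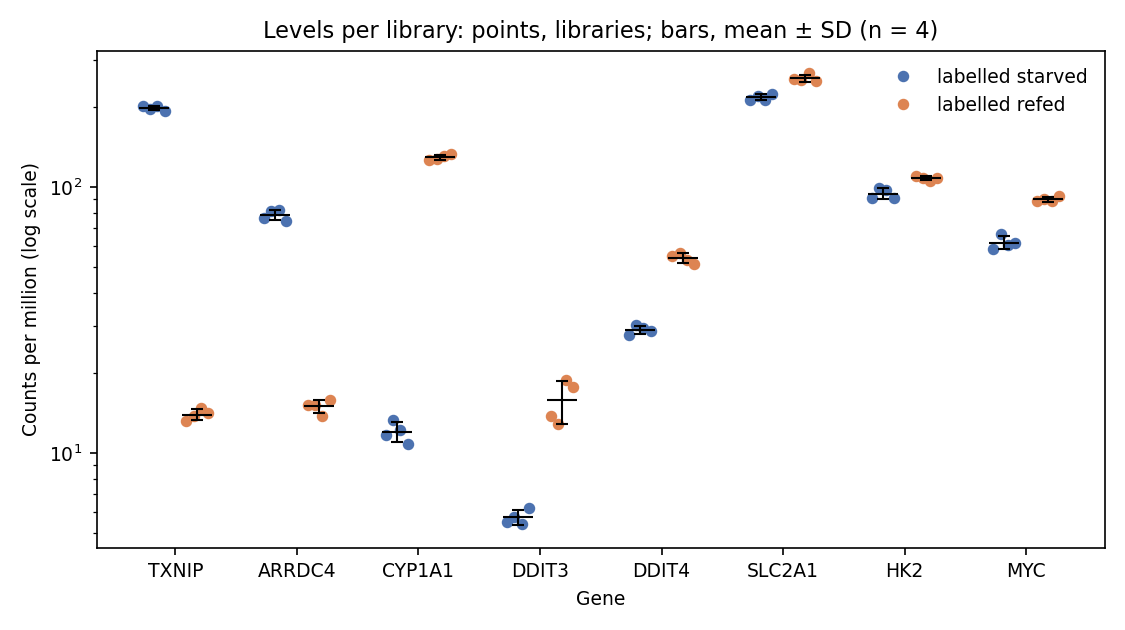
Levels of 8 named genes in each library, in CPM on a log axis, for the 4 libraries labelled starved (blue) and the 4 labelled refed (orange); each point is a library, and the black bars give the mean and SD. TXNIP stood at 199 CPM in labelled starved and 13.9 CPM in labelled refed and ARRDC4 at 78.6 and 15.0 CPM, while CYP1A1 stood at 12.02 and 129 CPM.

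Many genes differed between the groups, mostly by small amounts. With the edgeR quasi-likelihood test, 7636 of 16303 genes (46.8%) changed at an adjusted p under 0.05, of which 3716 were higher and 3920 lower in the libraries labelled refed. The median size of a called change was 0.38 on the log2 scale, a fold of 1.30. Changes shown to exceed 1.5-fold were found for 136 genes, 112 higher and 24 lower. That number was 90 without refed replicate 2, 78 with limma-voom, 79 with DESeq2 and 88 at an adjusted p under 0.01. The 4 values of one group lay entirely above the 4 of the other for 6726 genes (41.3%), where chance gives 2.86%. The first principal component held 45.2% of the variance and parted the groups. Libraries of different groups lay farther apart than libraries of one group by 0.14 log2 units (exact permutation test over 35 splits, p = 0.0286, the smallest these splits can give).

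The changes followed the GC content of the transcripts. Across the 16010 tested genes with an annotated transcript, log2 fold change and GC content had a Spearman correlation of 0.645, a relation across genes, which are not independent replicates. Of the 1603 genes lowest in GC (at most 38.6%), 1025 were lower and 25 higher in labelled refed. Of the 1601 genes highest in GC (at least 61.7%), 1034 were higher and 8 lower. For each library, log2 CPM was taken as the deviation from the gene's mean over all 8 libraries. The slope of this deviation on GC was 0.14 ± 0.06 per 10 points in the libraries labelled refed and -0.14 ± 0.05 in those labelled starved (SD, n = 4, exact two-sided permutation p = 0.0286, adjusted 0.0317 over 10 library measures). The centering makes these means mirror each other, so only their difference of 0.27 is informative. When the GC trend and that of transcript length were removed from each library, 5347 genes changed, 2571 higher and 2776 lower. Of these, 3630 were also called without the correction, 3301 in the same direction and 329 in the opposite one. Changes exceeding 1.5-fold then fell to 30 genes, 24 higher and 6 lower. Since the trend moves with the groups, values with GC and length removed, called corrected values, are given below as well. Of 89 named genes with a corrected log2 fold change, 47 came nearer to 0 by over 1.5 times and 2 moved away from it by over 1.5 times. Each of these is given with its corrected value.

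**Figure D2:**
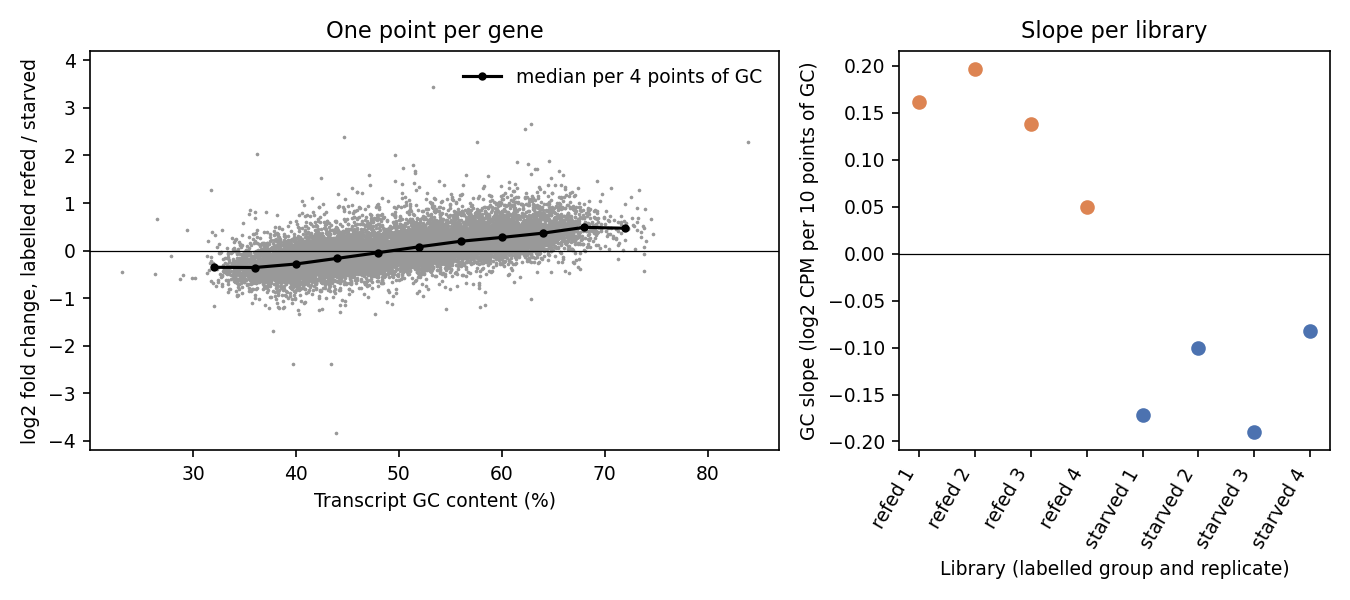
Left, log2 fold change of each gene (labelled refed over labelled starved) against the GC content of its transcript in percent, with the median per 4 points of GC as a line. Right, the slope on GC of log2 CPM in each library, taken as the deviation from the gene's mean over all libraries, orange for labelled refed and blue for labelled starved. The fold change rises with GC (Spearman 0.645 over 16010 genes), and the slopes of the 4 libraries labelled refed, 0.05 to 0.20, lie above those labelled starved, -0.19 to -0.08.

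Among the 12 largest increases in labelled refed, CYP1A1, a cytochrome P450 induced through the aryl hydrocarbon receptor, led with 129 ± 3.21 CPM against 12.02 ± 1.04 (10.8-fold, log2 fold change 3.43, SE 0.07, edgeR adjusted p = 5.583e-28; chromosome 15, 74719542 to 74725610, GRCh38). DDIT3, the stress-induced transcription factor CHOP, stood at 15.8 ± 2.91 against 5.71 ± 0.373 CPM (log2 fold change 1.46, SE 0.13), and 31.6% of its exon length overlaps a gene on the other strand. ACTL8, an actin-like protein, rose by 1.59 (SE 0.15) and PLEKHN1 by 1.35 (SE 0.13, corrected 0.89). Copies of the signal recognition particle RNA, RN7SL1 (2.66, SE 0.42) and RN7SL3 (2.56, SE 0.37), were also among them, as were the mitochondrial tRNA gene MT-TY (1.52, SE 0.29), the pseudogene PPP1R14BP3 (1.38, SE 0.13, corrected 0.84) and AL137001.2 (1.64, SE 0.15), which has no match in the annotation used. MRPL12 (1.89, SE 0.16), a mitochondrial ribosomal protein, TAF10 (1.73, SE 0.15), a subunit of TFIID, and ATP6V0C (1.33, SE 0.17, corrected 0.88), a subunit of the vacuolar proton pump, completed the 12. Reads of several of these genes could be shared with others: 68.2% of the exon length of MRPL12, 72.1% of that of ATP6V0C and 100% of that of RN7SL1 overlap another gene on the same strand, and 38.9% of that of TAF10 overlaps a gene on the other strand. The counting rules for such reads and the strand setting are not given in the sources used here. These values, and those of the RN7SL copies and the pseudogene, are therefore uncertain.

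Behind TXNIP and ARRDC4, the largest decreases in labelled refed included 4 genes of the interferon response. These were IFIT1 (log2 fold change -1.24, SE 0.25; 12.4 ± 3.33 against 29.2 ± 7.14 CPM), DDX58, which encodes the viral RNA sensor RIG-I (-1.06, SE 0.09), SAMD9 (-0.99, SE 0.12, corrected -0.58) and OAS2, an oligoadenylate synthetase (-0.97, SE 0.14). SLC6A14, an amino acid transporter, fell from 249 ± 16.6 to 112 ± 9.20 CPM (-1.15, SE 0.06). The others were Z83843.1 (-1.16, SE 0.15, corrected -0.73), the metalloproteinase MMP16 (-1.02, SE 0.10, corrected -0.60), NBEAL1 (-0.96, SE 0.11, corrected -0.57), the Rho GTPase regulator ARHGAP5 (-0.94, SE 0.09, corrected -0.49), part of which overlaps a gene on the other strand, and NFAT5, the transcription factor of the osmotic stress response (-0.93, SE 0.09, corrected -0.59). With GC and length removed, each of these 12 increases and 12 decreases kept its direction and its call, except AL137001.2, which has no transcript to correct by. The corrected values of TXNIP, ARRDC4 and CYP1A1 were -3.69, -2.19 and 3.30. Without the correction, RN7SL1, MT-TY, IFIT1 and OAS2 were not shown to change by more than 1.5-fold (glmTreat adjusted p = 0.0855, 0.148, 0.316 and 0.0825).

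Genes of the integrated stress response, which the factor ATF4 induces when nutrients are short or proteins misfold, were higher in labelled refed. Of 31 tested members 20 were higher and 3 lower, with a median log2 fold change of 0.36 (21 and 3 adjusted over the list alone). SLC7A5, the leucine transporter, stood at 1928 ± 82.3 against 987 ± 37.7 CPM (log2 fold change 0.97, SE 0.05), and its partner chain SLC3A2 stood at 757 ± 23.4 against 448 ± 34.04 CPM (0.76, SE 0.05, corrected 0.50). The stress cytokine GDF15 rose by 1.05 (SE 0.06, corrected 0.62), the mTORC1 inhibitor DDIT4 by 0.89 (SE 0.07) and the asparagine synthetase ASNS by 0.95 (SE 0.23). Of these, 41.2% of the exon length of DDIT4 overlaps a gene on the other strand and 44.6% of that of ASNS one on the same strand. The list shifted as a whole (camera adjusted p = 9.78e-07), and it was the only list to do so with an estimated correlation (adjusted p = 0.0274). With GC and length removed 18 members were higher and 4 lower, the median was 0.26, and the call with an estimated correlation was lost (adjusted p = 0.12).

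Immediate early genes and genes of ribosome production were higher in labelled refed. Of 38 tested immediate early genes, transcription factors and regulators that respond within minutes to serum and other stimuli, 19 were higher and 1 lower (20 and 1 adjusted over the list alone; camera adjusted p = 0.00015, adjusted p = 0.342 with an estimated correlation). JUN rose by 0.62 (SE 0.06), IER5 by 0.59 (SE 0.06), ZFP36, which destabilizes cytokine mRNAs, by 0.68 (SE 0.07, corrected 0.41), and MYC by 0.54 (SE 0.06), from 61.8 ± 3.42 to 89.98 ± 1.80 CPM. Of 40 ribosome biogenesis genes 21 were higher and 5 lower (21 and 6 adjusted over the list alone; camera adjusted p = 0.000432, adjusted p = 0.342 with an estimated correlation), among them WDR74 (0.84, SE 0.07), MYBBP1A (0.60, SE 0.06, corrected 0.32), RRS1 (0.58, SE 0.06, corrected 0.33) and RRP9 (0.65, SE 0.07, corrected 0.29). Of 33 cytosolic ribosomal proteins 20 were higher and 2 lower (camera adjusted p = 3.03e-06, adjusted p = 0.572 with an estimated correlation), including RPS2 (0.57, SE 0.05, corrected 0.30), RPS11 (0.46, SE 0.05, corrected 0.21), RPL7A (0.39, SE 0.04) and RPS14 (0.40, SE 0.05). Ribosomal protein genes held 5.79 ± 0.135% of all counts in labelled refed against 4.91 ± 0.175% in labelled starved (exact two-sided permutation p = 0.0286, adjusted 0.0317, n = 4 per group). Of 14 snoRNA host and nonsense-mediated decay sensitive transcripts 9 were higher and 0 lower (camera adjusted p = 0.00241, adjusted p = 0.572 with an estimated correlation). None was lower with edgeR at an unadjusted p under 0.05, limma-voom or DESeq2 either. SNHG12 stood at 0.81 (SE 0.08), SNHG15 at 0.58 (SE 0.07), SNHG7 at 0.59 (SE 0.07, corrected 0.13) and GAS5 at 0.27 (SE 0.05, corrected 0.43). Uncorrected medians of the 4 lists were 0.28, 0.23, 0.18 and 0.22 in this order. The corrected ones were 0.12, 0.17, 0.13 and 0.24, with camera adjusted p = 0.00246, 3.56e-09, 0.000127 and 3.34e-06, and no list passed with an estimated correlation. Corrected counts were 15 higher and 3 lower for immediate early genes and 18 higher and 6 lower for ribosomal proteins, while 24 ribosome biogenesis genes and 12 snoRNA host and decay-sensitive transcripts were higher.

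Among metabolic lists, cholesterol synthesis and glycolysis shifted, with medians of 0.14 and 0.13. Of 25 cholesterol synthesis genes 13 were higher and 4 lower (camera adjusted p = 0.0365, adjusted p = 0.342 with an estimated correlation), including MVD (0.73, SE 0.06, corrected 0.33), PMVK (0.64, SE 0.08, corrected 0.29) and TM7SF2 (0.56, SE 0.07, corrected 0.15), enzymes of the pathway, and the LDL receptor LDLR (0.51, SE 0.06). That call was lost without refed replicate 4 (adjusted p = 0.0702) and with genes of a mean CPM of at least 5 alone (adjusted p = 0.0614). Of 23 glycolysis and lactate export genes 11 were higher and 1 lower (camera adjusted p = 0.0373, adjusted p = 0.572 with an estimated correlation). PFKL (0.52, SE 0.05, corrected 0.18), PFKP (0.39, SE 0.05, corrected 0.15) and TPI1 (0.33, SE 0.05), enzymes of the pathway, were higher, and LDHA, a lactate dehydrogenase chain, was lower (-0.31, SE 0.05, corrected -0.18). The glucose transporter SLC2A1 rose by 0.24 (SE 0.05, corrected 0.09), a call lost with GC alone removed (0.08, edgeR adjusted p = 0.102), and HK2, which phosphorylates glucose, by 0.19 (SE 0.05). The glycolysis call was lost without refed replicate 1, refed replicate 4 or starved replicate 4 (adjusted p = 0.0518, 0.0577 and 0.069). With GC and length removed 7 members were higher and 5 lower (adjusted p = 0.594), TPI1 no longer passing the test (0.06, edgeR adjusted p = 0.169). Corrected counts of cholesterol synthesis were 14 higher and 2 lower, with a median of 0.16 (adjusted p = 0.00136, and 0.195 with an estimated correlation). Of 17 purine and pyrimidine synthesis genes 8 were higher, including DHODH (0.72, SE 0.08) and PFAS (0.46, SE 0.06, corrected 0.25), and 5 lower (camera adjusted p = 0.43). The corrected counts of 9 and 2 passed the list test (adjusted p = 0.024, and 0.195 with an estimated correlation). Of 26 genes of hexosamine and N-glycan precursor synthesis 5 were higher and 11 lower (5 and 14 adjusted over the list alone), including GFPT1 (-0.49, SE 0.06, corrected -0.11), the first enzyme of the hexosamine pathway, and OGT (-0.34, SE 0.05, corrected -0.10). That list did not shift (camera adjusted p = 0.21), and 3 members were higher and 5 lower with the correction. The pentose phosphate pathway (4 higher and 1 lower of 7; 5 and 1 adjusted over the list alone) and fatty acid synthesis (6 and 5 of 16) did not shift as lists either (camera adjusted p = 0.0825 and 0.806), but the pentose phosphate list passed without starved replicate 3 (adjusted p = 0.0397). Corrected counts were 2 and 2 for the pentose phosphate pathway and 2 and 3 for fatty acid synthesis.

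Protein-coding transcripts of the mitochondrial genome were lower in labelled refed, unlike the tRNA gene MT-TY above. Of 13 tested 11 were lower and 0 higher, with a median of -0.36 (camera adjusted p = 1.77e-07, adjusted p = 0.342 with an estimated correlation). Without the correction none was higher with edgeR at an unadjusted p under 0.05, limma-voom or DESeq2 either. With it 11 were lower and 1 was higher, MT-ND3 (-0.01, corrected 0.11), named after its values were seen. The lower ones included MT-ND4L (-0.61, SE 0.05), MT-CO2 (-0.39, SE 0.04), MT-CYB (-0.38, SE 0.04) and MT-ND4 (-0.40, SE 0.05). Genes of the mitochondrial chromosome held 7.21 ± 0.380% of counts in labelled refed and 8.71 ± 0.0841% in labelled starved (exact two-sided permutation p = 0.0286, adjusted 0.0317, n = 4 per group). The corrected median was -0.28 (camera adjusted p = 3.56e-09, adjusted p = 0.195 with an estimated correlation). Nuclear-encoded respiratory chain genes did not shift as a list: 11 of 32 were higher and 5 lower (camera adjusted p = 0.27), including NDUFV1 (0.58, SE 0.06, corrected 0.28) and COX5B (0.46, SE 0.06, corrected 0.24). With the correction 12 were higher and 5 lower (adjusted p = 0.031, and 0.195 with an estimated correlation).

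Protein-folding lists went both ways. Of 23 genes of endoplasmic reticulum (ER) chaperones and the unfolded protein response, 9 were higher and 6 lower (camera adjusted p = 0.354). The higher ones included HSPA5, the main chaperone of the ER, at 812 ± 39.0 against 669 ± 28.4 CPM (0.28, SE 0.05), CALR (0.43, SE 0.05, corrected 0.26), SDF2L1 (0.68, SE 0.08, corrected 0.16), HYOU1 (0.44, SE 0.05) and CRELD2 (0.54, SE 0.07). With GC and length removed 12 were higher and 3 lower, and the list passed (adjusted p = 0.000157, and 0.195 with an estimated correlation). Of 20 heat shock genes 5 were higher and 8 lower, the latter including HSPH1 (-0.49, SE 0.05, corrected -0.18), DNAJA1 (-0.44, SE 0.05, corrected -0.25), CHORDC1 (-0.61, SE 0.08, corrected -0.20) and HSPA8 (-0.33, SE 0.04). The list did not shift (camera adjusted p = 0.453, and 0.15 with corrected counts of 3 and 10). Of 22 NRF2 antioxidant genes 9 were higher and 8 lower (10 and 10 adjusted over the list alone; camera adjusted p = 0.59, with a median of -0.05 and a mean of 0.09), and the corrected counts were 9 and 7. OSGIN1 rose by 1.23 (SE 0.07), the cystine transporter SLC7A11, also a member of the stress response list, by 0.77 (SE 0.09, corrected 1.20) and the ferritin chain FTH1, of which 62.4% of the exon length overlaps a gene on the other strand, by 0.55 (SE 0.06), while AKR1C1 fell by 0.85 (SE 0.09). Of 24 p53 target genes 11 were higher, GDF15 and the apoptosis gene BBC3 (1.18, SE 0.10, corrected 0.63) among them, and 6 lower, TP53INP1 (-0.79, SE 0.07, corrected -0.47) among them (11 and 7 adjusted over the list alone; camera adjusted p = 0.27). The corrected counts of 8 and 3 passed (adjusted p = 0.0449, and 0.205 with an estimated correlation).

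Of 22 genes of G2/M and mitosis, 3 were higher and 10 lower, including TOP2A (-0.44, SE 0.06), ASPM (-0.44, SE 0.07), KIF11 (-0.37, SE 0.06) and CENPE (-0.41, SE 0.07), but the list did not shift (camera adjusted p = 0.174). These AT-rich transcripts came near 0 with GC and length removed: TOP2A stood at -0.10, ASPM and KIF11 at -0.03 and CENPE at 0.02, the last 3 no longer passing the test. The corrected counts of the list were 4 higher and 2 lower. G1/S genes gave 6 higher and 5 lower of 22 (camera adjusted p = 0.857), and 3 and 6 with the correction.

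Markers of the line's own cell type went both ways. Of 15 luminal epithelial markers 4 were higher, ELF3 (0.39, SE 0.06, corrected 0.22) and CLDN4 (0.29, SE 0.05, corrected 0.08) among them, and 5 lower. ESR1, the estrogen receptor, stood at 233 ± 9.70 against 311 ± 15.4 CPM (-0.41, SE 0.05, corrected -0.28) and AGR2 at 209 ± 8.29 against 275 ± 12.6 CPM (-0.39, SE 0.05, corrected -0.21). The list did not shift (camera adjusted p = 0.788), whereas with GC and length removed 11 members were lower and 1 higher (adjusted p = 0.000127, and 0.12 with an estimated correlation), CLDN4 no longer passing. Of 9 basal and mesenchymal markers with enough counts 1 was higher and 1 lower (camera adjusted p = 0.745), and 2 were higher with the correction. Of the leukocyte and endothelial markers 4 could be tested. None passed with edgeR over all genes, adjusted over the list alone or at an unadjusted p under 0.05, nor with limma-voom or DESeq2. Other measures of whole libraries parted the groups. The number of genes detected was 26821 ± 373 in labelled refed and 25704 ± 283 in labelled starved (SD, n = 4). Non-coding genes held 1.19 ± 0.0220% and 1.09 ± 0.0253% of counts and the 20 most abundant genes 13.2 ± 0.353% and 14.2 ± 0.152%. The slope per doubling of transcript length, with GC in the model, was -0.03 ± 0.01 and 0.03 ± 0.01 for log2 CPM taken as the deviation from the gene's mean over all libraries. Each of these differed with an exact two-sided permutation p = 0.0286 (adjusted 0.0317, n = 4 per group). The lists fixed as checks of RNA quality did not shift: 1 of 6 nuclear-retained RNAs was higher and 1 lower (camera adjusted p = 0.857), and 5 of 16 replication-dependent histone genes were higher and 1 lower (camera adjusted p = 0.354; corrected counts of 1 and 1). With GC and length removed, however, 4 of the 6 nuclear-retained RNAs were higher (adjusted p = 0.00515, and 0.195 with an estimated correlation).

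The other lists did not shift with or without the correction. Counts higher and lower were 4 and 7 of 20 for cytosolic aminoacyl-tRNA synthetases (camera adjusted p = 0.893), 8 and 7 of 31 for autophagy and lysosome genes (0.745), 6 and 5 of 19 for hypoxia genes outside glycolysis (0.857; 6 and 6 adjusted over the list alone), and 3 and 6 of 20 for FOXO targets (0.831). For the autophagy and G1/S lists the median was negative (-0.01 and -0.05) and the mean and the test positive (means of 0.03 and 0.01). For hypoxia genes the median of 0.09 and the mean were positive and the test negative. Counts were 10 and 8 of 27 for the estrogen response (0.651), 6 and 2 of 14 for NF-kB and inflammatory cytokine genes (0.389), and 8 and 4 of 19 for the circadian clock (0.408). Corrected counts higher and lower were 6 and 6 for the synthetases, 6 and 8 for autophagy and lysosome genes, and 6 and 6 for hypoxia genes. They were 10 and 9 for the estrogen response, 2 and 1 for NF-kB genes and 8 and 2 for the clock. For FOXO targets the balance turned, to 6 higher and 2 lower, and the median went from -0.03 to 0.04 (camera adjusted p = 0.412). The medians of hypoxia, estrogen response and NF-kB genes also changed sign, from 0.09, 0.04 and 0.11 to -0.08, -0.04 and -0.02, and those of autophagy and lysosome genes and the synthetases from -0.01 and -0.0036 to 0.01 each. Elsewhere the medians of the MondoA and ChREBP list and of G2/M genes changed sign, from 0.09 and -0.12 to -0.03 and 0.01, and those of fatty acid synthesis and histone genes went from 0.08 and 0.11 to just below 0. Where no second count is given, the count adjusted over the list alone was the same as that over all genes tested. In total 8 of 31 lists with at least 5 tested members shifted, 7 up and 1 down, and 14 did so with GC and length removed, 11 up and 3 down. With an estimated correlation these numbers were 1 and 0.

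**Figure D3:**
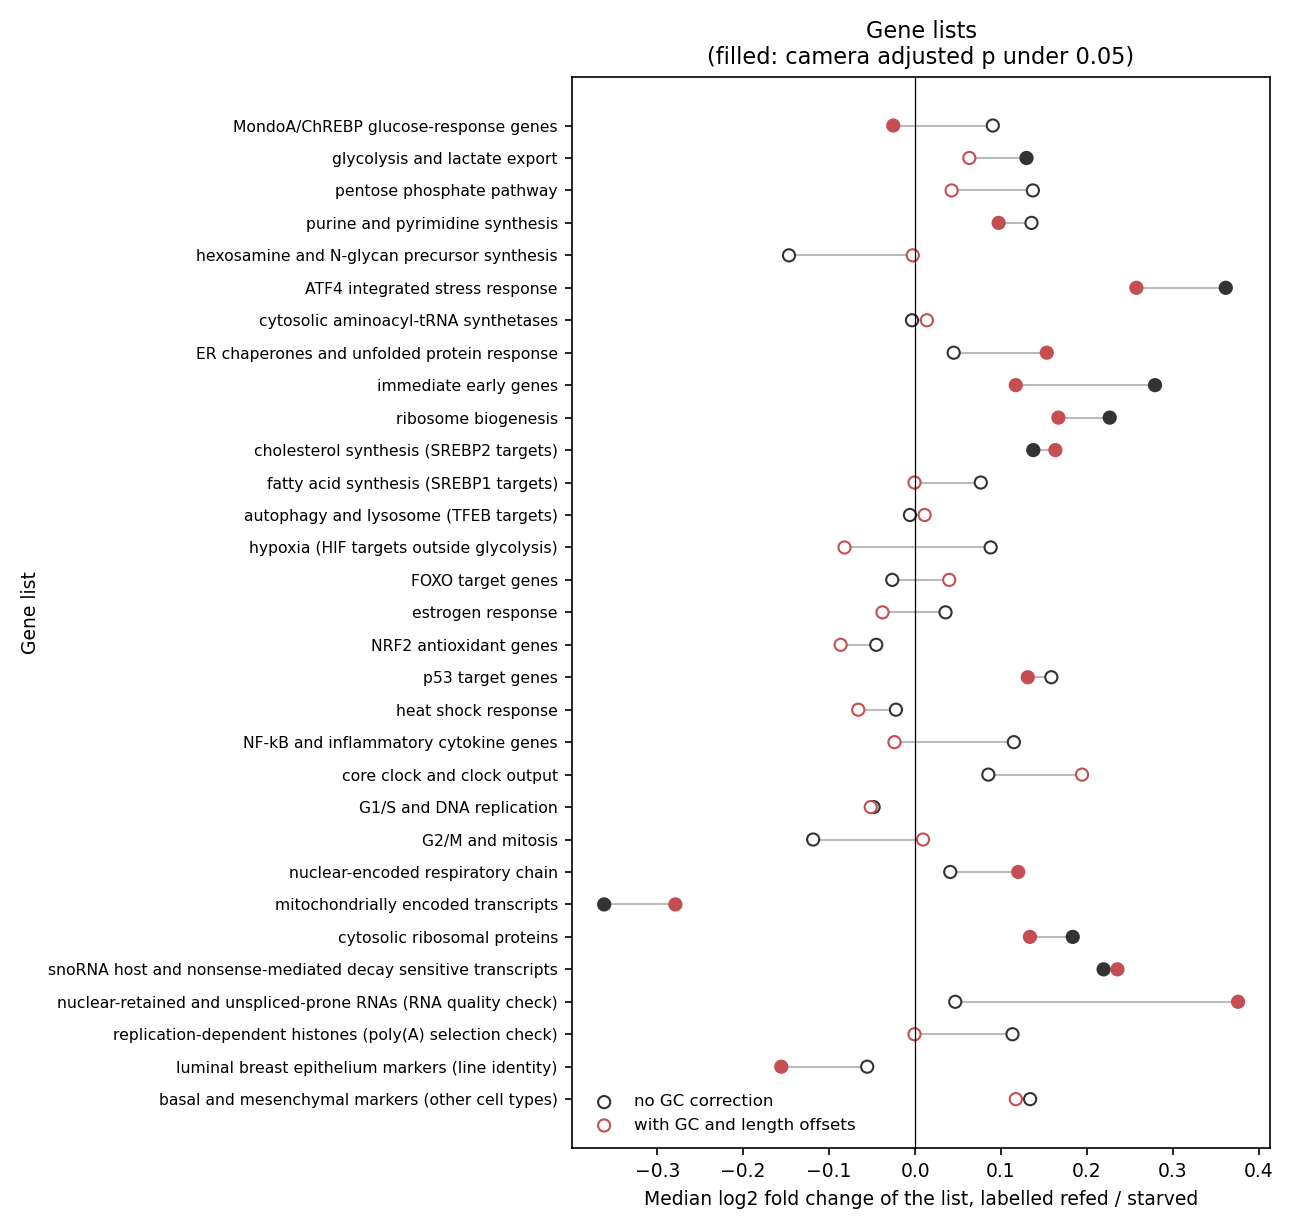
Median log2 fold change (labelled refed over labelled starved) of the tested genes of each of 31 lists, without correction (black) and with GC and length trends removed (red); filled points have a camera adjusted p under 0.05 with the preset correlation. Integrated stress response genes had a median of 0.36 without and 0.26 with the correction, and mitochondrially encoded transcripts -0.36 and -0.28.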

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

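The tests of the labels and of GC content for TXNIP, the tests of GC slopes in non-coding RNAs and of gene length, and the addition of GC and length offsets were chosen after the results were seen. The test that sets untranslated against coding sequence addresses the GC trend, so it too was added after that trend was seen. For this test and for the counts of other splits, the prediction was written before the value was computed.

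Among 196 groups of 4 libraries tested, from 90 named genes and 8 library measures, 8 held a library far from the others (a gap to the nearest, as a share of the group's range, above Dixon's 95% limit); chance gives about 1 in 20, or 9.8. In refed replicate 4, PFKP was low at 292 CPM (others 332 to 338), HSPH1 was high at 226 CPM (208 to 210) and TOP2A was high at 177 CPM (155 to 158). HSPA8 was low in refed replicate 2 at 1746 CPM (1870 to 1890) and high in starved replicate 3 at 2404 CPM (2274 to 2296). CHORDC1 was low in starved replicate 4 at 36.01 CPM (42.5 to 43.4). Refed replicate 3 had the fewest counts in its group, 14702280 in total (18456053 to 18967990). Ribosomal protein genes held 4.65% of counts in starved replicate 1 (4.98% to 5.01%).

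TXNIP and ARRDC4 were far lower in the libraries labelled refed, although glucose is known to induce both. Single mislabelled libraries are argued against, since the lowest labelled starved CPM was 13.2 times the highest labelled refed CPM for TXNIP and 4.72 times for ARRDC4, and so is the GC and length trend, with TXNIP at a log2 fold change of -3.69 after its removal. An exchange of all the labels of the groups stays open. After correction, stress response genes that glucose withdrawal is known to induce had a median of 0.26 (camera adjusted p = 6.64e-07, but adjusted p = 0.12 with an estimated correlation). Of 23 ER chaperone and unfolded protein response genes, 12 were then higher and 3 lower in labelled refed (camera adjusted p = 0.000157, but adjusted p = 0.195 with an estimated correlation). Both go the way such an exchange would need. The ER list did not pass without the correction, however (9 higher and 6 lower, camera adjusted p = 0.354). The list of cytosolic aminoacyl-tRNA synthetases did not shift, with 6 higher and 6 lower of 20 after correction (camera adjusted p = 0.831). Against an exchange, 24 of 40 ribosome biogenesis genes were also higher in labelled refed (camera adjusted p = 3.56e-09, but adjusted p = 0.139 with an estimated correlation). So were 15 of 38 immediate early genes, with 3 lower and a median of 0.12 (camera adjusted p = 0.00246, but adjusted p = 0.195 with an estimated correlation). Renewed complete medium could give such changes, although immediate early genes also respond to other stimuli and so bear less on the question. A biological effect of refeeding itself was not tested and stays open too, since the time in complete medium is not given in the sources used here.

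Fold changes rose with transcript GC content, by 0.28 log2 units per 10 points over 14305 genes with a mean CPM of at least 1. Gene length and span are argued against, since the slope kept 0.934 (SE 0.0104) of its size with both in the model. A change tied to the coding sequence is argued against, since GC in 3′ untranslated regions had 0.905 (SE 0.0351) of the coefficient of coding GC over 9724 genes. A GC-dependent bias in library preparation or sequencing is a candidate explanation: other RNAs, pseudogenes included, had 0.841 (SE 0.0385) of the slope of protein-coding genes, so they share most of it, although a bias wholly blind to coding would give equal slopes and this one is lower by more than its error. The slopes part by group, so a biological effect that follows GC in coding and non-coding RNA alike stays open and untested.

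The number of genes changed could be set apart from chance: 1 of 35 splits of the 8 libraries, the real one, called 7636 genes and the highest of the others called 0. For changes beyond 1.5-fold it was again 1 of 35, with 136 genes against 0. For gene lists the count of splits did not exclude chance: 2 of 35 splits shifted 8 or more, the highest other 11, which paired refed replicate 1 with starved replicates 1, 2 and 4. That split keeps part of the difference between the groups, so its 11 lists do not show what chance alone gives. Splits with 2 libraries of each group on either side shifted at most 3 lists. The splits test only whether the groups differ, not whether glucose or another difference between the groups is the reason. Every other split mixes the groups, so the group difference widens the spread within its sides and makes calls of genes unlikely. The 0 therefore does not show how many of the 7636 calls are right.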

How the results depend on the processing

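The GC corrections were chosen after the data were seen; the other alternatives were not. The number of genes changed stayed between 5286 (GC removed) and 7857 (without refed replicate 4), within 1.5 times of 7636. The distance between the groups kept its sign and its permutation p under each alternative run for it. That p is already the smallest the splits can give, so it cannot show how far the size of the distance changed. The split of higher and lower calls moved by under 10 percentage points, at most to 55.6% higher with upper-quartile factors. The number of genes changed by more than 1.5-fold, 136, was 29 with GC removed, 30 with GC and length removed, 78 with limma-voom, 79 with DESeq2 and 88 at an adjusted p under 0.01, and from 90 (without refed replicate 2) to 192 (without refed replicate 4) with 1 library left out. For the GC settings the trend removed shows the cause; for the others the cause was not tested. Of the gene lists, 8 shifted, against 14 with GC and 14 with GC and length removed, 1 with an estimated correlation and 21 with fry, which does not compare a list with other genes; leaving out 1 library gave 6 to 9. Of 90 named genes, 7 lost their call under some setting and none did so outside the GC corrections. The 1 that reversed was CENPE, at 0.0186 with GC and length removed, where its call ended. Named genes were mostly chosen for clear changes in the main fit, so their stability does not extend to all calls. Without refed replicate 2, for example, 6555 of the 7636 genes were called again. Whether replicate numbers pair the libraries was not settled. After each group's gene means were subtracted, same-numbered libraries correlated by 0.025, 0.068, -0.016 and -0.093, and 2 of the 4 libraries labelled refed correlated best with their own number. Subtracting the means draws such correlations toward 0, so the check cannot exclude a pairing. With the replicate block 7391 genes were called, 137 changed beyond 1.5-fold, and 8 lists shifted. With the libraries thinned to the smallest one, 7446 genes were called. In simulated libraries of this depth 40% of the smallest changes tried were recovered, so depth and replication limit what can be seen of small changes.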

Other observations

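The tests in this part were chosen after the results were seen, and so were both gene lists, which were taken from general knowledge once CYP1A1 and IFIT1 had stood out. Being among the members, these genes count partly as a repeat of what prompted the lists.

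Of 7 tested targets of the aryl hydrocarbon receptor, a ligand-activated transcription factor, 5 were higher and 0 lower in the libraries labelled refed, and none was lower with edgeR at an unadjusted p under 0.05, limma-voom or DESeq2 either. After removal of GC and length 6 were higher. CYP1B1, which with CYP1A1 is among the best known targets, stood at 591 ± 45.2 CPM (SD, n = 4) against 258 ± 13.3 CPM (log2 fold change 1.19, SE 0.05), and AHRR, the repressor of the receptor, at 9.54 ± 1.07 against 5.49 ± 0.767 CPM (0.80, SE 0.13). The increase was uneven across members. TIPARP rose by 0.19 (SE 0.07, corrected 0.39), and ALDH3A1 had few counts (0.956 against 0.348 CPM). NQO1 (0.11) and UGT1A6 (0.17) did not pass, although NQO1 did with the correction (0.19). Since CYP1A1 prompted the list, the test was run without it. Of the other 6 members 4 were higher, with a median of 0.49 (camera p = 0.00267, and p = 0.0389 with an estimated correlation). After that removal 5 were higher, with a median of 0.50 (camera p = 1.6e-05, and p = 0.0105 with an estimated correlation).

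Of 39 tested interferon-stimulated genes 21 were lower in the libraries labelled refed and 1, ISG20, was higher, with a median of -0.54 (camera p = 1.85e-06, but p = 0.157 with an estimated correlation). Without IFIT1, OAS2, DDX58 and SAMD9, which are among the largest decreases, 17 of 35 were lower and 1 higher, with a median of -0.35 (camera p = 8.13e-05, but p = 0.196 with an estimated correlation). STAT1, a transcription factor of the response, stood at 205 ± 3.48 against 298 ± 7.33 CPM (-0.54, SE 0.05, corrected for GC and length -0.35), EIF2AK2, the RNA-activated kinase PKR, fell by 0.79 (SE 0.06, corrected -0.42), and IFIT3 fell by 1.30 (SE 0.19). The list members STAT2 and IRF9 did not pass (-0.0003 and -0.04, edgeR adjusted p = 0.998 and 0.794). MX1, a classical member, did not pass (0.13, corrected 0.04, edgeR adjusted p = 0.69). Nor did ISG15 without the correction (-0.08, edgeR adjusted p = 0.58).

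The GC and length trend is argued against as the whole cause of the decrease of interferon-stimulated genes: with it removed 26 members were lower and 1 higher and the median was -0.43, and without the 4 genes named above it was -0.38, although the list tests gave p = 0.0761 and 0.0804 with an estimated correlation. The count of 26 rests in part on the correction itself. ISG15 (-0.08, GC 63.4%), IRF7 (0.03, 66.85%) and BST2 (0.06, 57.3%) passed as lower only with it (-0.55, -0.46 and -0.25). The same held for TAP1 (-0.03, 57.5%), UBE2L6 (0.06, 57.2%), IFI6 (-0.06, 56.1%) and TRIM21 (-0.35, 50.9%), with corrected values of -0.27, -0.21, -0.36 and -0.43. In turn HERC6 and XAF1 lost their calls. Each member that passed as lower without the correction, OAS3 (54.3%) included, had a lower GC content than the genes that passed only with it, TRIM21 excepted. A single library is argued against too, since with any 1 library left out the median stayed at -0.48 or lower. A biological difference between the labelled groups is a candidate explanation that was not tested, and its direction depends on the labels.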
